A study of Drosophila melanogaster with 10 samples.

How the data were processed

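The series holds 10 one-colour Affymetrix arrays of whole Drosophila melanogaster larvae of the 3rd instar, taken before or 4 h after injection of the bacterium Staphylococcus saprophyticus. Per the labels, total RNA was extracted and biotinylated cRNA was hybridised to the arrays. Groups were read from the sample titles and genotype labels: yw larvae and larvae carrying the Gyc76C allele KG03723 with 2 biological replicates in each state, and larvae of the genotype Dif/Dl[J4] with 1 array in each state. The p-values of single probe sets therefore rest on the spread between biological replicates, pooled over the groups with 2 arrays. Groups with 1 array were not tested. P-values of gene lists at a preset correlation depend mainly on the spread between genes. Fisher's exact test and exact intervals count genes or probe sets and hold no spread between larvae.

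The deposited table gives 1 intensity per probe set and array on a linear scale, which the submitters' processing notes credit to MAS5. The version of MAS5, its target value, detection calls and masking are not given in the sources used here. The deposited intensities showed how the arrays had been scaled, because the mean after trimming 2% of the probe sets at each end was 500 on every one of the 10 arrays. Such scaling sets a common level per array and hides any change in the total amount of mRNA. Median signals ranged from 109 to 132, the 40th percentile from 49.0 to 66.1 and the highest signal from 34828 to 44506. For arrays no count depth applies, and their number limits the precision.

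The table holds 18952 probe sets, of which 183 are control probe sets and were left out of the tests. A probe set to gene table of the array platform named 1 gene for 13646 probe sets, several for 402 and none for 1, and did not list 4903, of which 4720 are not controls. Current symbols were sought through the gene identifiers against the RefSeq annotation of the assembly Release 6 plus ISO1 MT, which updated 0 symbols and left 103 as the platform table gives them. The named probe sets cover 11981 genes. No gene is named from a probe set with several genes, and genomic coordinates are not given here because no build is named with the values. That annotation served for names, for the chromosome of a gene, and for the order of neighbouring genes by their start positions.

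Values were analysed as log2(signal + 16), so a log2 change understates the change of genes with low signal. Probe sets were kept where the signal reached the 40th percentile of its array on at least 2 of the 10 arrays, which left 12114 of 18769. No further normalization was applied to the deposited intensities. A linear model with 1 mean for each of the 6 groups was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes with an intensity trend, which left 4 residual and 4.17 prior degrees of freedom. There were 5 tested comparisons: the response to injection in yw, the response in Gyc76C mutants, the difference of these responses, and Gyc76C against yw before and after injection. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The standard error (SE) given beside a log2 change is limma's moderated one.

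A total of 23 gene lists, covering immune pathways, cGMP signalling, cell type and tissue markers, stress, moulting and metabolism, were fixed from general knowledge, and 22 had the minimum of 3 measured members. They were tested with camera in limma at a preset correlation of 0.01 between genes, with 1 probe set per gene, the one with the highest mean over all arrays, and adjustment over the 22 lists of a comparison. Each list was also tested by camera with an estimated correlation and by fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, one way. Of the 10 lists called in yw, the 10 called in Gyc76C mutants, the 1 called for the difference of responses, and the 3 and 3 called between genotypes before and after injection, 0 were called with an estimated correlation. By fry, 7 of the 10, 7 of the 10, 0, 0 and 0 of them were called. A call lost with an estimated correlation does not by itself show that the genes of a list were correlated. For IMD pathway components in yw the estimate was 0.0089, below the preset 0.01. Their unadjusted camera p still went from 0.000714 to 0.0271. For the single Dif/Dl arrays, the log2 difference of each gene was taken, and the median of a list was placed by its percentile among 10000 random lists of the same size matched on mean expression.

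The genes named in each tested comparison were drawn from the 12 with the highest and the 12 with the lowest log2 change among those called, or, with fewer than 5 called in a direction, those of lowest p up to 5. Up to 6 members of each list with the largest absolute change, and the genes Gyc76C, Dif, dl, y and w, could be named as well. Some genes were named outside this rule, such as Drs in yw and BomBc3 in Gyc76C mutants, which had the smallest changes of their list. For Dif/Dl, the rule takes the 10 highest and 10 lowest differences and the members of both effector lists. Where other probe sets of a named gene differ in their call, this is stated.

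The model was tested on simulated arrays with 200 of the 12114 probe sets changed by a known amount, in 20 simulations. For the response in yw, 59.6% of changes of 1 log2 unit and 96% of changes of 2 log2 units were recovered, with 10.2 false calls on average. For the difference of responses, the shares were 13.2% and 82.6%, with 6.6 false calls.

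Alternatives covered the pseudocount (1 or 64), the filter (none, or the 60th percentile), quantile normalization, median centring, eBayes without the trend, array weights, only the 8 yw and Gyc76C arrays, the replicate number as a block, other thresholds, and leaving out each of the 8 arrays in turn, where the lone array left in a group is assumed to vary like the other groups. Gene lists, groups, tests, the rule for named genes, and these alternatives for the counts of calls and for both effector lists were chosen before the data were examined. Gene mapping and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. A comparison with uninjected or sham-injected larvae kept for the same 4 h was not analysed here, so the effects of injection, of 4 h of time and of infection cannot be told apart in any response given here.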

Results

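Transcripts of whole larvae were measured in 3 genotypes before and 4 h after injection of the Gram-positive bacterium Staphylococcus saprophyticus. Larvae of the yw strain served as the control genotype. The Gyc76C mutant carries an allele of a receptor-type guanylate cyclase, a membrane enzyme that makes cGMP, and Dif/Dl[J4] affects Dif and dl (dorsal), which encode NF-kappaB factors of the Toll pathway. Replicate arrays correlated at r = 0.981 and 0.986 in yw before and after injection and at 0.97 and 0.968 in Gyc76C mutants, across probe sets on the log2 scale. The highest correlation between arrays of different groups was 0.974, so some arrays of different groups were as alike as replicates of the mutant.

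The genotypes were checked first through the genes they concern. The signal of dl was lower in Dif/Dl larvae than in yw on both of its probe sets. It was 201 before and 284 after injection against means of 595 and 624 on one, and 257 and 445 against 398 and 871 on the other. The only probe set for Dif stayed below the low-signal limit (the 40th percentile of the array) in all groups, with 22.9 and 27.7 in Dif/Dl larvae and 45.1 and 33.1 in yw. No probe set names Gyc76C alone, since the 3 annotated to it are shared with another gene, so the array does not check that genotype. The body pigment gene y was below the filter, with means of 12.7 and 15.3 in yw, 61.1 and 40.3 in Gyc76C mutants and single values of 19.5 and 15.6 in Dif/Dl larvae.

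In yw larvae, injection was followed by a rise of Toll-dependent secreted peptides, of stress peptides and of several pathway genes, and by a fall of cuticle genes. The Turandot gene TotC, a secreted stress peptide, rose from a mean signal of 27.6 ± 0.221 to 6639 ± 292 (SD, n = 2), a log2 change of 7.25 (SE 0.28, adjusted p = 2.36e-05). The Bomanin genes encode short peptides induced by the Toll pathway. They rose by 7.25 for BomS2 (SE 0.72, adjusted p = 0.00168), 7.16 for BomBc2 (SE 0.76), 7.03 for BomT2 (SE 0.17, adjusted p = 1.15e-06) and 6.63 for BomS5 (SE 0.50). The serine protease homologue gene CG33462 rose by 6.48 (SE 0.45), CG42792 by 6.13 (SE 0.43) and TotB by 5.18 (SE 0.48). Of the 12114 probe sets tested, 696 were called, 356 higher and 340 lower, and 2737 had an unadjusted p under 0.05. The called probe sets name 293 genes that rose and 291 that fell, while 95 have no single gene.

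Among the fixed lists, all 10 measured Toll pathway effectors of 19 listed rose, also when adjusted over the list alone, with a median log2 change of 4.80 (camera adjusted p = 4.23e-14, and adjusted p = 0.151 with an estimated correlation). Their changes ranged from 3.51 for the antifungal peptide gene Drs (SE 0.63) to 7.25 for BomS2. Of 8 measured IMD pathway effectors, 2 rose, or 6 when adjusted over the list alone (median 2.16, adjusted p = 0.00063, and adjusted p = 0.229 with an estimated correlation). The antibacterial peptide genes DptB and AttD rose by 4.34 (SE 0.59) and 2.46 (SE 0.52), whereas edin (5.34, SE 1.31, adjusted p = 0.0538), PGRP-SB1 (2.68), CecB (1.86) and Def (1.03, adjusted p = 0.421) were not called. Of 8 JAK-STAT and stress peptide genes, 5 rose, or 7 when adjusted over the list alone (median 1.97, adjusted p = 1.06e-06, and adjusted p = 0.151 with an estimated correlation). Beside TotC and TotB these were TotZ (3.44), TotF (2.85) and vir-1 (1.09). Among 19 Toll pathway components, 3 rose, or 5 adjusted over the list alone. They were the serpin gene nec (1.54, SE 0.14), the receptor gene Tl (1.21, SE 0.14) and dl (1.10, SE 0.19), whose second probe set was not called (0.07, SE 0.15). That list had a median of 0.35 (adjusted p = 9.06e-05, and adjusted p = 0.151 with an estimated correlation). The NF-kappaB gene Rel rose by 1.45 (SE 0.16), the only one called of 13 IMD pathway components, with 4 adjusted over the list alone (median 0.44, adjusted p = 0.00225, and adjusted p = 0.151 with an estimated correlation).

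The largest falls in yw were those of CG3348 (-4.65, SE 0.40) and the cuticle genes TwdlO (-4.50, SE 0.33) and Lcp65Af (-4.22, SE 0.30). They were followed by CG10560 (-3.75), Cpr78Cc (-3.60), CG10953 (-3.37), the vitamin transporter gene Smvt (-3.32), CG1441 (-3.22), TwdlP (-3.21) and Cpr65Aw (-3.19). Of 13 cuticle genes of the list, 5 fell, or 9 adjusted over the list alone (median -0.95, adjusted p = 1.09e-05, and adjusted p = 0.151 with an estimated correlation). Of 15 larval fat body genes, Idgf1 (1.35, SE 0.27) and Idgf3 (0.70, SE 0.12) rose and ACC (-2.04, SE 0.19) and FASN1 (-1.59, SE 0.12) fell, and of 21 carbohydrate and lipid metabolism genes InR (1.02, SE 0.20) rose and AcCoAS (-1.77, SE 0.18) fell. Neither list was called (adjusted p = 0.9 and 0.065). Blood cell genes went both ways: PPO1 (-0.94), PPO2 (-1.18) and Pxn (-1.35) fell, and He (1.0) rose, with 1 rise and 1 fall among 14 plasmatocyte markers, or 5 and 2 adjusted over the list alone.

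Camera also called 4 lists in yw of which 0 genes were called by limma over all probe sets. These were JNK and wound response (median 0.37, adjusted p = 0.00501, and adjusted p = 0.422 with an estimated correlation) and body wall muscle (-0.44, 0.000582 and 0.508), and also salivary gland secretion (-0.30, 0.00573 and 0.166) and cell cycle (-0.21, 0.0278 and 0.424). Adjusted over the list alone, 2 JNK and wound genes rose and 1 fell, and 1, 2 and 1 genes fell in the other lists in that order. The cell cycle call was lost without yw replicate 2 before injection (median -0.12, adjusted p = 0.0888) and without yw replicate 1 after it (median -0.10, adjusted p = 0.135). Among the lists not called were cGMP signalling (median 0.08, adjusted p = 0.828), melanisation (0.35, 0.702), plasmatocyte markers (0.13, 0.803), crystal cell and lamellocyte markers (0.18, 0.83), and heat shock (0.20, 0.803). The same held for ecdysone and prepupal genes (0.04, 0.828), larval fat body (0.07, 0.9) and midgut digestive enzymes (-0.09, 0.828). Testis (0.03, 0.976), neurons (0.23, 0.12), detoxification (0.06, 0.58) and carbohydrate and lipid metabolism (-0.23, 0.065) were not called either. Median and mean had opposite signs for crystal cells (mean -0.11), ecdysone genes (-0.06), midgut enzymes (0.02) and detoxification (-0.14).

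A group left with 1 array weakens the test whichever array is left out. The number of calls in yw was lower without either yw array after injection. It was 127 and 162 without yw replicates 1 and 2 before injection, and at most 982. Of the 51 named genes called in yw, 19 were called in all 8 fits that left out 1 array: TotC, TotB, BomS2, BomBc2, BomT2, BomS5, CG33462, CG42792, nec, CG3348, TwdlO, TwdlP, Lcp65Af, CG10560, Smvt, CG1441, ACC, FASN1 and AcCoAS. Tl and Rel lost their calls without yw replicate 2 after injection (adjusted p = 0.0506 for both), and DptB without either yw array after injection (highest adjusted p = 0.0871, log2 4.27). AttD, dl and PPO2 were called in none of the fits that left out a yw array, with adjusted p up to 0.2, 0.157 and 0.234, and the same held for TotZ, PPO1 and Cpr65Aw (up to 0.0845, 0.305 and 0.151) and for Idgf1, Idgf3 and InR (up to 0.163, 0.18 and 0.208). TotF and He lost their calls without yw replicate 2 before injection or either yw array after it (adjusted p up to 0.119 and 0.0651). Pxn lost its call without either yw array before injection or replicate 2 after it (up to 0.102), and vir-1 without either before it or replicate 1 after it (up to 0.0659). Cpr78Cc lost its call without yw replicate 1 before injection (adjusted p = 0.0564) and CG10953 without yw replicate 2 after it (adjusted p = 0.0669).

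**Figure D1:**
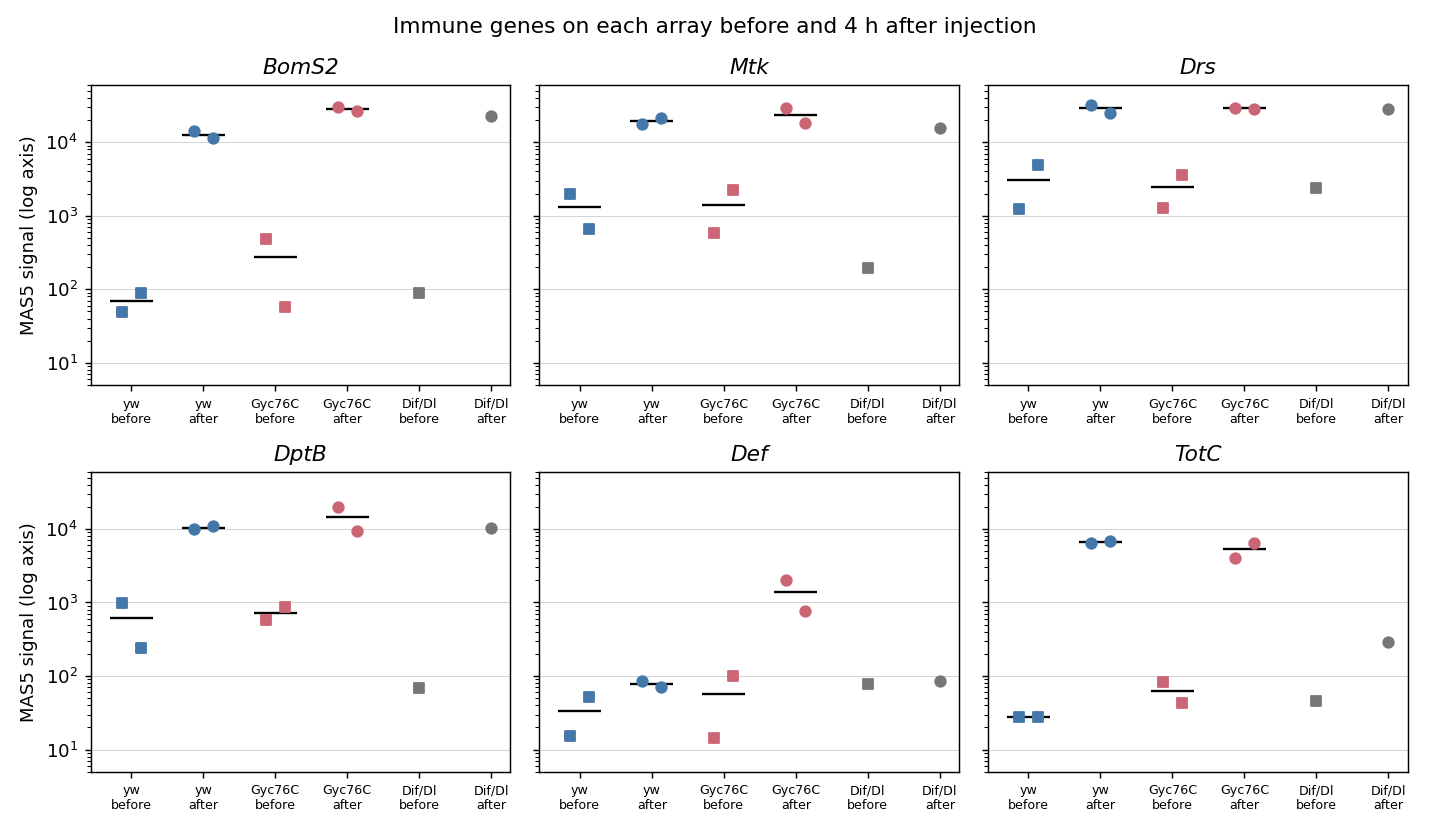
MAS5 signal (log axis) of 6 immune genes on each array, by genotype and state; points are single arrays and black bars the mean of 2 arrays, and Dif/Dl has 1 array per state. BomS2, Mtk and Drs lay higher after injection on every array of each genotype. TotC reached 6639 and 5287 on average in yw and Gyc76C larvae and 293 on the Dif/Dl array, and Def reached 1391 on average in Gyc76C larvae and 77.8 in yw.

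Bomanin and Turandot genes also led the response in Gyc76C mutants. The Bomanin genes BomS2, BomBc2, BomT2 and BomS5 rose by 7.20 (SE 0.72), 7.10 (SE 0.76), 6.51 (SE 0.17, adjusted p = 2.17e-06) and 6.30 (SE 0.50). TotC rose by 6.09 (SE 0.28, adjusted p = 6.48e-05), with n = 2 per state. Mtk, an antimicrobial peptide gene, rose by 4.32 (SE 0.65), Def, the defensin gene, by 4.40 (SE 0.68, adjusted p = 0.0171), Bbd by 4.22 (SE 0.23) and DptB by 4.22 (SE 0.59). The largest falls were again in cuticle genes, with Lcp65Af at -4.80 (SE 0.30), Cpr47Eg at -4.71 (SE 0.66), TwdlN at -4.08 (SE 0.77) and TwdlO at -4.06 (SE 0.33). Of 12114 probe sets, 235 were called, 133 higher and 102 lower, naming 104 and 90 genes, with 37 that have no single gene and 1996 at an unadjusted p under 0.05.

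Of the 10 measured Toll pathway effectors, 9 rose in Gyc76C mutants, or 10 adjusted over the list alone (median 4.20, adjusted p = 1.49e-17, and adjusted p = 0.114 with an estimated correlation). The one not called over all probe sets was BomBc3 (3.72, SE 0.81, adjusted p = 0.0663). Of 8 IMD pathway effectors, Def, DptB and AttD (2.93, SE 0.52) rose, or 6 genes adjusted over the list alone (median 3.29, adjusted p = 9.58e-06, and adjusted p = 0.143 with an estimated correlation). Toll pathway components (median 0.42, adjusted p = 2.45e-06, and adjusted p = 0.125 with an estimated correlation) had 3 of 19 members called, or 5 adjusted over the list alone. Those called were nec (1.83, SE 0.14), Tl (1.09, SE 0.14) and the Toll ligand gene spz (0.81, SE 0.15). Rel rose by 1.51 (SE 0.16), the only one called of 13 IMD pathway components and the only one adjusted over the list alone (median 0.30, adjusted p = 0.00553, and adjusted p = 0.143 with an estimated correlation). TotC, TotB (4.41, SE 0.48) and vir-1 (0.98, SE 0.15) rose among 8 JAK-STAT and stress genes, with 7 adjusted over the list alone (median 1.56, adjusted p = 2.33e-09, and adjusted p = 0.125 with an estimated correlation).

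Of 13 cuticle genes, Lcp65Af, Lcp65Ae (-2.44, SE 0.37) and Lcp65Ac (-1.76, SE 0.23) fell in the mutants. Adjusted over the list alone, 10 fell and 2 rose (median -1.03, adjusted p = 3.83e-07, and adjusted p = 0.128 with an estimated correlation). Digestive enzymes of the midgut had a median of -0.56 (adjusted p = 4.25e-07, and adjusted p = 0.269 with an estimated correlation), with 24 of 29 members below 0. The trypsin gene thetaTry (-2.94, SE 0.30) and the lysozyme gene LysS (-1.22, SE 0.23) fell, or 9 genes adjusted over the list alone. Of 15 larval fat body genes, Idgf3 rose (0.76, SE 0.12) and FASN1 (-1.20, SE 0.12) and ACC (-1.20, SE 0.19) fell, and of 21 carbohydrate and lipid metabolism genes AcCoAS fell (-0.92, SE 0.18). Neither list was called (adjusted p = 0.907 and 0.212). Camera also called JNK and wound response (0.22, adjusted p = 0.0423, and adjusted p = 0.582 with an estimated correlation), salivary gland secretion (-0.23, 0.00755 and 0.154) and body wall muscle (-0.35, 0.00328 and 0.586). In these limma called 0 genes over all probe sets, and adjusted over the list alone 2 JNK and wound genes rose and 1 fell. Each of the 3 calls was lost in more than 1 fit that left out an array. Without Gyc76C replicate 2 after injection the adjusted p was 0.434 for JNK and wound response and 0.418 for muscle. Without Gyc76C replicate 2 before injection it was 0.0704 for salivary gland secretion. Of the 12 lists not called, melanisation came closest (0.48, adjusted p = 0.101), and cGMP signalling had a median of 0.06 (adjusted p = 0.959).

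Gyc76C replicate 1 after injection stood apart from replicate 2 in CG7924 (8.0 against 4223), CG7906 (119 against 4530) and CG14664 (36.6 against 3674, and 683 against 3947 before injection). In the ecdysone-induced gene Eip78C, replicate 1 was the lower one both before (21 against 224) and after injection (33.4 against 233). Among the 8 fits that left out 1 array, calls in Gyc76C mutants were fewest without Gyc76C replicate 1 before injection. They were most without Gyc76C replicate 1 after injection. They also became fewer without either yw array after injection. Of the 40 named genes called, 24 were called in all 8 such fits, among them 5 Bomanin genes, TotC, TotB, Bbd, nec, Tl, Rel, FASN1, thetaTry, Lcp65Af, TwdlO and TwdlP. Def lost its call without yw replicate 1 or 2 after injection (highest adjusted p = 0.0556) and without Gyc76C replicate 1 before injection, and Mtk without either yw array after injection (highest adjusted p = 0.051). DptB and Cpr47Eg lost theirs without Gyc76C replicate 1 before injection (adjusted p = 0.0653 and 0.0662), and spz and Idgf3 in each of the 8 fits (adjusted p up to 0.149 and 0.0967). LysS, AttD and AcCoAS were called in 1, 2 and 1 of the 8, with adjusted p up to 0.179, 0.0819 and 0.127, and TwdlN in 3 (adjusted p up to 0.153). Without Gyc76C replicate 1 before injection vir-1 (adjusted p = 0.073) and ACC (adjusted p = 0.0785) were lost, and Lcp65Ae without either Gyc76C array before injection (adjusted p up to 0.0634).

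**Figure D2:**
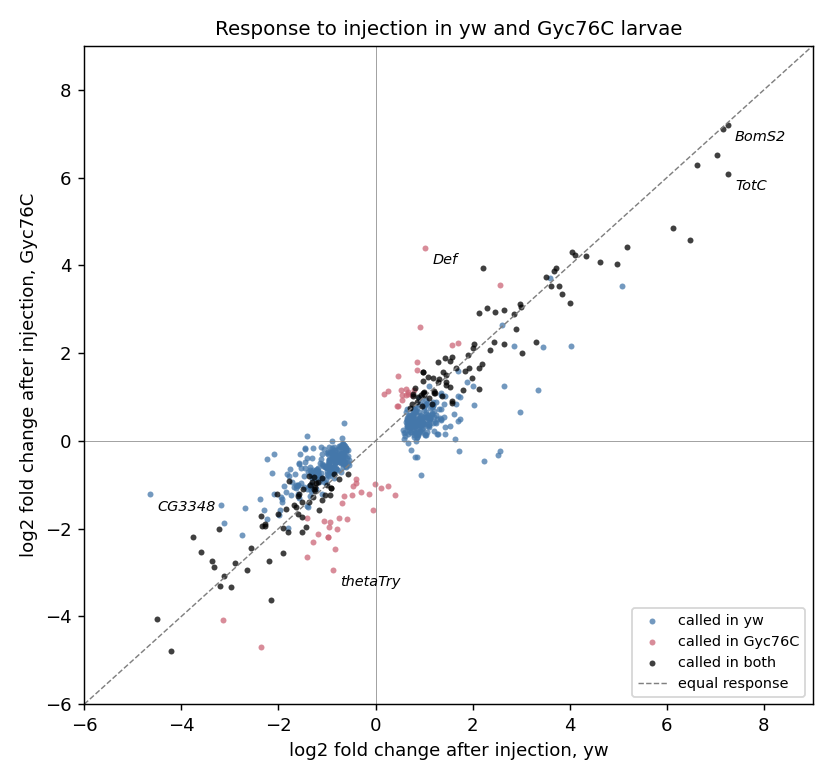
Log2 change after injection in yw (horizontal axis) and in Gyc76C mutants (vertical axis) for genes called in either; each point is a gene, black points were called in both, and the dashed line marks equal responses. TotC (7.25 and 6.09) and BomS2 (7.25 and 7.20) lie at the upper end, and Def (1.03 and 4.40) and CG3348 (-4.65 and -1.22) lie apart from the line, although no difference of responses was called.

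Whether the mutation altered the response was tested by the difference of responses, Gyc76C minus yw. In it 0 of 12114 probe sets were called by limma (lowest adjusted p = 0.816), with 581 at an unadjusted p under 0.05, or 4.8%. The log2 difference was -0.05 for BomS2, with a 95% interval from -2.40 to 2.30 for each single gene taken alone, 0.21 for Drs (-1.83 to 2.26), 0.26 for Mtk (-1.85 to 2.37) and -0.12 for DptB (-2.03 to 1.78). These 4 intervals leave room for differences of several fold in either direction. BomT2, the most precise of the Toll effectors, differed by -0.53 (-1.09 to 0.03). The differences of lowest p were Root (1.28), CG3348 (3.43), SCaMC (1.02), Kal1 (1.06) and CG10073 (1.82) on the higher side. On the lower side they were CG9672 (-1.73), Rcd2 (-1.12), CG4716 (-2.33), Cyp6a17 (-1.18) and Prx6a (-1.05), all at adjusted p from 0.816 to 0.858. Def had a difference of 3.37 (SE 0.96, interval 1.17 to 5.58, adjusted p = 1) and TotC one of -1.17 (-2.08 to -0.26, adjusted p = 1). Leaving out 1 array gave 0 calls in 6 of 8 fits, 4 without Gyc76C replicate 2 before injection and 2 without Gyc76C replicate 2 after injection.

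Neither effector list was called for the difference of responses, with medians of -0.05 for Toll (adjusted p = 0.596) and 0.22 for IMD effectors (adjusted p = 0.596). The IMD list had a median of 1.02 (adjusted p = 0.00907) without Gyc76C replicate 2 after injection and turned to -0.24 without replicate 1 after injection and -0.08 without replicate 1 before it. The Toll list ranged from -0.73 to 0.40 in such fits. Digestive enzymes were the only list called of 22, with a median difference of -0.63 (adjusted p = 3.14e-08, and adjusted p = 0.847 with an estimated correlation) and 25 of 29 genes below 0. Limma called 0 of them, or 1 adjusted over the list alone, with thetaTry at -2.06, Jon74E at -1.81, LysX at -1.55 and alphaTry at -1.49. Its median was -0.29 without Gyc76C replicate 1 before injection (adjusted p = 0.0113). The mean log2 signal of these enzymes per array was 11.32 and 11.26 in yw before and 11.30 and 11.32 after injection, and 12.06 and 11.46 before and 11.10 and 11.17 after injection in Gyc76C mutants. On the single Dif/Dl arrays it was 11.76 before and 11.40 after injection.

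Across all probe sets the log2 changes of yw and Gyc76C larvae correlated at r = 0.76, a correlation across genes, which are not independent replicates. Of the probe sets called, 178 were shared in the same direction and 0 in opposite directions, where lists drawn independently would share 6.77. Of the 696 called in yw, 97.6% had the same sign in the mutants. Among the 202 probe sets that rose at least 2-fold in yw the median log2 change was 1.49 in yw and 1.08 in Gyc76C mutants, and among the 182 that fell at least 2-fold it was -1.47 and -1.03. These probe sets were selected by their change in yw, which by itself favours larger values there, and the difference of these medians was not tested.

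Before injection, 169 probe sets differed between Gyc76C and yw larvae, 110 higher and 59 lower in the mutants, naming 87 and 47 genes, with 32 that have no single gene and 1512 at an unadjusted p under 0.05. The gene CG3777 was higher by 6.94 (SE 0.25, adjusted p = 1.34e-05), from a mean signal of 5.51 in yw to 2618 in the mutants (n = 2 each), and the cytochrome P450 gene Cyp4p2 by 6.47 (SE 0.36). The detoxification genes Cyp6g1, a P450 known from insecticide resistance, Cyp6a9 and GstE7 were higher by 4.54 (SE 0.50), 2.98 (SE 0.31) and 2.81 (SE 0.35), and GstE9 was lower by -2.42 (SE 0.31), with its other probe set not called. CG32198 was lower by -6.91 (SE 0.22, adjusted p = 9.3e-06), from 18020 in yw to 133 in the mutants, followed by CG9040 (-3.78), CG10073 (-3.58), hpRNA:CR32207 (-3.48) and Rnf11 (-2.53). Further genes higher in the mutants were CG8160 (4.20), CG7300 (4.02), CG31769 (3.68), COX6AL2 (3.04) and Cyp6a23 (2.53).

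Of the lists, midgut digestive enzymes were higher in the mutants before injection (median 0.37, adjusted p = 0.000724, and adjusted p = 0.818 with an estimated correlation), with 3 of 29 genes called, or 8 adjusted over the list alone. Among the 3 were the trypsin genes betaTry (2.05, SE 0.29) and epsilonTry (1.95, SE 0.33). Plasmatocyte markers were lower (median -0.33, adjusted p = 0.00294, and adjusted p = 0.394 with an estimated correlation), with 1 of 14 called, the phagocytosis receptor gene NimC1 (-1.80, SE 0.17). Adjusted over the list alone, 4 were lower and 1 higher. Larval fat body genes were lower (median -0.13, adjusted p = 0.0294, and adjusted p = 0.818 with an estimated correlation), with 1 of 15 called, ACC (-1.05, SE 0.19), or 3 adjusted over the list alone. Of 10 Toll pathway effectors, BomT2 alone was called (1.04, SE 0.17), and the list was not (median 0.57, adjusted p = 0.141), although it was called without Gyc76C replicate 2 (0.99, adjusted p = 0.0103) or yw replicate 2 (0.98, adjusted p = 0.00933) before injection and turned to -0.11 (adjusted p = 0.84) without Gyc76C replicate 1 before injection. Of 31 detoxification genes, 4 were higher and 2 lower, or 5 and 10 adjusted over the list alone (median -0.27, adjusted p = 0.0601, not called).

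The number of differences before injection was 28 and 29 without yw replicates 1 and 2 before injection, 61 without Gyc76C replicate 1 before injection, 69 and 70 without yw replicates 2 and 1 after injection, and at most 214. Of the 29 named genes called, 12 were called in all 8 such fits: CG3777, Cyp4p2, CG8160, CG7300, CG31769, COX6AL2, CG32198, CG9040, CG10073, hpRNA:CR32207, Rnf11 and NimC1. Cyp6g1, Cyp6a9, Cyp6a23 and GstE7 were not called without either yw array before injection (adjusted p up to 0.0719, 0.0535, 0.0706 and 0.0929). BomT2, ACC, betaTry, epsilonTry and GstE9 were also lost without those arrays, with adjusted p up to 0.198, 0.274, 0.151, 0.221 and 0.111. The midgut list was not called without Gyc76C replicate 1 before injection (0.30, adjusted p = 0.142), nor the fat body list without yw replicate 2 (-0.10, adjusted p = 0.0516) or Gyc76C replicate 2 before injection (-0.18, adjusted p = 0.0959).

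After injection, 79 probe sets differed between the genotypes, 42 higher and 37 lower in Gyc76C mutants, naming 30 and 26 genes, with 22 that have no single gene and 978 at an unadjusted p under 0.05. CG3777 (5.72, SE 0.25), Cyp4p2 (5.61, SE 0.36), Cyp6g1 (4.02, SE 0.50), CG7300 (3.80), CG8160 (3.71), CG31769 (3.55) and GstE7 (3.29, SE 0.35) were again higher. Again lower were CG32198 (-7.54, SE 0.22), hpRNA:CR32207 (-3.78, SE 0.21), Rnf11 (-3.61, SE 0.19) and CG9040 (-3.38, SE 0.34). Other genes higher after injection were CG3348 (3.08, and -0.36 before injection), Prx6c (2.98, and 1.82 before) and the neprilysin-like gene Nepl3 (2.55, SE 0.22, and 2.0 before). Lower were CG30087 (-2.66, and -0.49 before), Miox (-2.37, and -1.48), Hpd (-2.13, and -1.13), the chitinase gene Cht9 (-1.92, and -1.72) and the odorant-binding protein genes Obp69a (-1.92, and -1.82) and Obp49a (-1.89, and -0.92). Of these, Prx6c, Nepl3, Miox, Cht9 and Obp69a were also called before injection. Of the probe sets called before and after injection, 53 were shared in the same direction and 0 in opposite directions, where independent lists would share 0.562, and 95.3% of those called before injection had the same sign after it.

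Plasmatocyte markers were again lower after injection (median -0.19, adjusted p = 0.00807, and adjusted p = 0.424 with an estimated correlation), with NimC1 called (-1.64, SE 0.17) and 4 genes adjusted over the list alone. Fat body genes (median -0.20, adjusted p = 0.0226, and adjusted p = 0.795 with an estimated correlation) were lower and testis genes (0.25, adjusted p = 0.0195, and adjusted p = 0.795 with an estimated correlation) higher. In either list limma called 0 genes over all probe sets. Toll and IMD pathway effectors were not called as lists (0.35, adjusted p = 0.369, and 0.54, adjusted p = 0.222). Adjusted over the list alone, 1 IMD effector was called, Def at 3.75 (adjusted p = 0.0645 over all probe sets). The IMD list was called without Gyc76C replicate 2 after injection (1.17, adjusted p = 0.00207) and turned to -0.02 (adjusted p = 0.909) without replicate 1 after injection, as the Toll list did to -0.05. Midgut enzymes were not called (-0.06, adjusted p = 0.244).

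Here too, a group left with 1 array weakens the test whichever array is left out. In the 8 fits that left out 1 array, genotype differences after injection were fewer without either yw array after injection. They were also fewer without Gyc76C replicate 1 after injection. Of the 26 named genes called, 9 were called in all 8 such fits: CG3777, Cyp4p2, CG7300, CG8160, CG31769, Nepl3, CG32198, hpRNA:CR32207 and Rnf11. NimC1, GstE7, CG9040, Miox and Cht9 were lost without yw replicate 1 after injection (adjusted p = 0.0857, 0.0857, 0.0805, 0.0536 and 0.0589), and Prx6c without yw replicate 2 after injection (adjusted p = 0.0685). Cyp6g1, CG3348, Hpd, CG30087, Obp69a and Obp49a were lost without either of these arrays, with adjusted p up to 0.191, 0.16, 0.359, 0.456, 0.093 and 0.119. Without yw replicate 1 after injection the plasmatocyte markers (-0.12, adjusted p = 0.227), larval fat body (-0.03, adjusted p = 0.644) and testis lists (0.14, adjusted p = 0.644) were not called. Fat body and testis were also lost without Gyc76C replicate 1 after injection (adjusted p = 0.119 and 0.456).

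The Dif/Dl larvae cannot show whether the response needs these factors, because part of the dl signal remained. Its 2 probe sets lay at 0.338 and 0.645 of the yw mean before injection, and at 0.456 and 0.511 after it. Dif was too low to judge. With 1 array per state the differences also have no replicate check. The Toll pathway effectors were higher after injection, with a median log2 difference of 6.0 over 10 genes (range 3.53 to 7.74, percentile 100 among 10000 random lists). BomBc2 and BomS2 were both higher by 7.74, BomT2 and BomS5 by 6.99, Mtk by 6.22, BomS6 by 5.79 and Drs by 3.53, from 2399 to 27920, against 3.51 in yw. Of IMD pathway effectors, DptB was higher by 6.95, edin by 4.26 and PGRP-SB1 by 3.94, Def by 0.13, and the list had a median of 1.19 (percentile 100). The stress peptide genes differed less than in yw: TotC went from 46.3 to 293, a difference of 2.31 against 7.25 in yw, and TotB from 21.6 to 14.1. TotZ and TotF differed by 0.21 and 0.65 (list median 0.49, percentile 99.2).

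Other lists in Dif/Dl larvae included cuticle (median -0.70, percentile 0), midgut digestive enzymes (-0.43, percentile 0.05), detoxification (-0.52, percentile 0), body wall muscle (-0.68, percentile 0.39) and ecdysone and prepupal genes (0.60, percentile 100). These percentiles rank a list among other genes and hold no spread between larvae. The median difference in Dif/Dl larvae minus the change in yw, not tested, was -1.30 for stress peptides (range -5.50 to 0.70), 0.34 for Toll effectors (-0.68 to 2.16), -0.30 for Toll pathway components (-0.80 to 0.37), -0.47 for midgut enzymes (-2.18 to 1.14) and 0.67 for ecdysone and prepupal genes (-0.99 to 4.23). For IMD effectors it was -0.59, with members both ways, from AttD (-1.19) to DptB (2.61). The highest differences outside the effector lists were those of CG7924 (6.24), CG7906 (5.67) and CG14664 (4.93), whose signals before injection were 2.52, 20.8 and 27.7 against means of 2039, 2236 and 1271 in yw. These genes were also low on Gyc76C replicate 1 after injection, so the Dif/Dl array before injection was not alone in this. That Dif/Dl array was low as well in the ecdysone-induced gene Eip78C (12.9, against 144 after injection), as Gyc76C replicate 1 was in each state. The lowest were those of CG31089 (-3.32), CG10553 (-3.17), CG10560 (-3.12) and Smvt (-3.04). Of the probe sets called in yw, 94.8% had the same sign in Dif/Dl larvae, and the log2 changes correlated at r = 0.67 across all probe sets. Their median difference in Dif/Dl larvae was 0.987 for those that rose at least 2-fold in yw and -1.16 for those that fell.

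**Figure D3:**
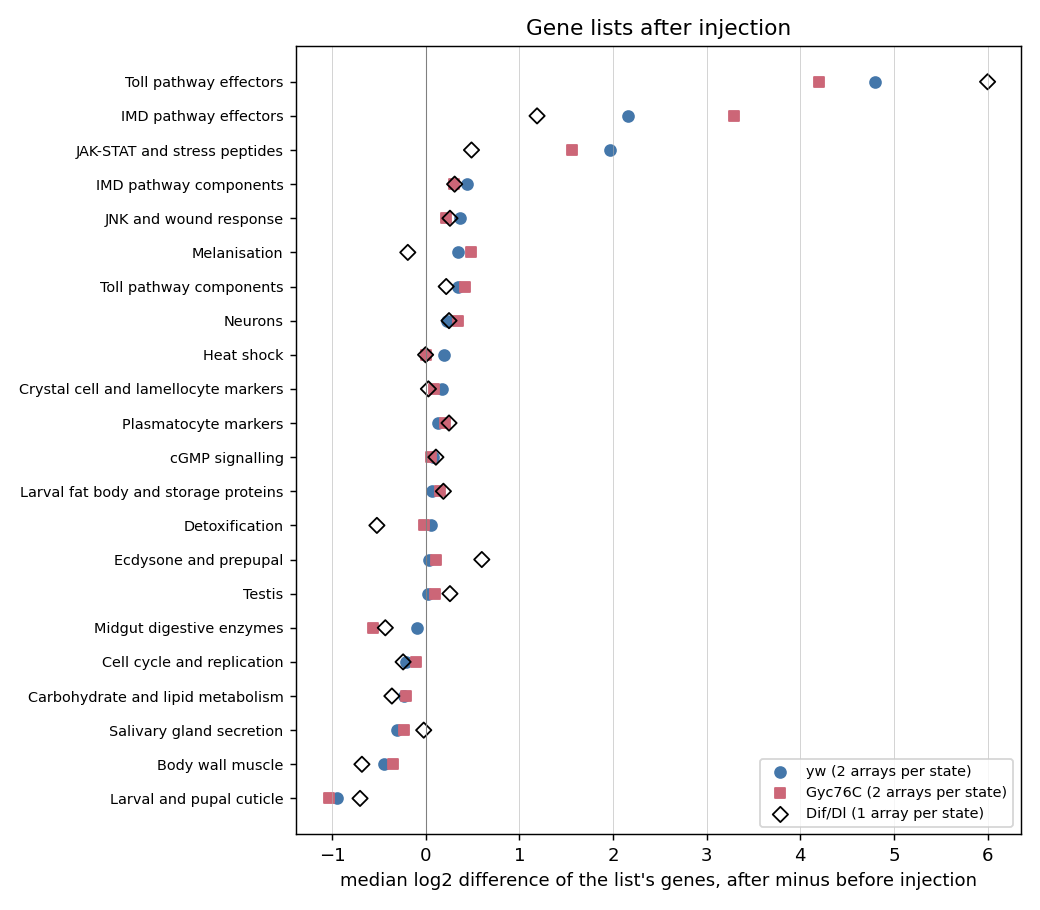
Median log2 difference after minus before injection of the genes of each list, in yw, Gyc76C and Dif/Dl larvae; each symbol is the median over the measured members of 1 list. Toll pathway effectors lie at 4.80, 4.20 and 6.0, stress peptides at 1.97, 1.56 and 0.49, cuticle genes at -0.95, -1.03 and -0.70, and midgut enzymes at -0.09, -0.56 and -0.43.

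**Figure D4:**
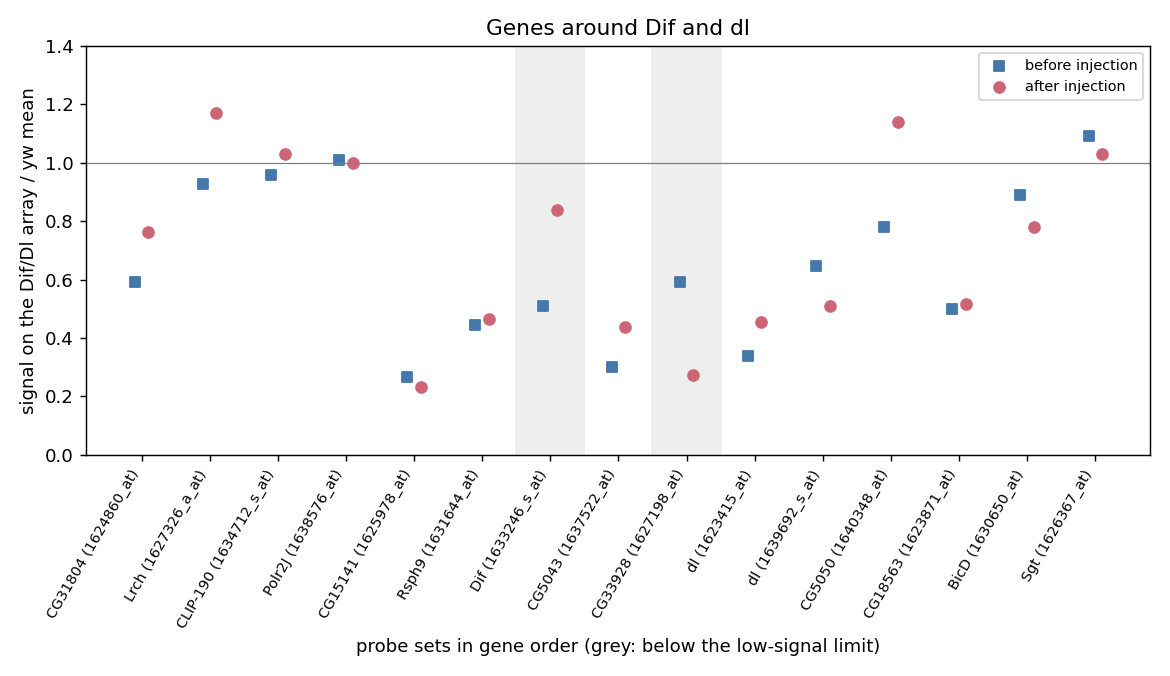
Signal on the Dif/Dl arrays divided by the yw mean for probe sets in gene order around Dif and dl, before (squares) and after injection (circles). The line at 1 marks equal signal and grey bands mark probe sets below the low-signal limit; CG15141 lies at 0.266 and 0.232 and the 2 probe sets of dl at 0.338 and 0.456 and at 0.645 and 0.511, whereas Polr2J, a few genes away, lies at 1.01 and 1.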

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

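The tests of enzyme levels before injection, of loss of Gyc76C alone, of chromosome 3, of the Dif and dl window and of remaining transcription, and those of gene families, were chosen only after the result was seen. The single-array, midgut share, Gyc76C segment and scanner range tests had their bounds written before their values were seen. In all, 9 explanations were tested over 3 patterns, beside the 22 lists and 17 gene families tested in each comparison.

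Digestive enzyme genes of the midgut stood out because their response differed between the genotypes, with a median log2 difference of -0.63 over 29 genes (Gyc76C minus yw; adjusted p = 3.14e-08, and adjusted p = 0.847 with an estimated correlation), and it was -0.47 for Dif/Dl minus yw, without a test. For a single array as the whole cause, the difference was called in all 8 fits that left out 1 array (highest adjusted p = 0.0113). These calls cannot decide the question, because they rest on the preset correlation and the list was not called with an estimated one. The median stayed below 0 in these fits, from -0.90 to -0.29, the latter without Gyc76C replicate 1 before injection. That array had a mean log2 enzyme signal of 12.06, against 11.46 in its replicate, so a large part may rest on it. For a different share of midgut tissue, other midgut genes had a mean difference of -0.32 (95% interval -0.50 to -0.14, 16 genes) against -0.64 (-0.88 to -0.41) for the enzymes, which met the bound written beforehand against this explanation. These intervals run over genes measured on the same arrays and hold no spread between larvae, so they cannot decide the question. That bound was also judged too loose after these values were seen, because 14 of the 16 other midgut genes lay below 0. The intervals overlap as well, so a different share of midgut tissue stays open. Enzyme levels that differed before injection stay open as well. The list was higher in Gyc76C mutants then (median 0.37, camera adjusted p = 0.000724, but adjusted p = 0.818 with an estimated correlation) and was not called afterwards. Its median was 0.30 without Gyc76C replicate 1 before injection. This cannot decide the question, because the difference of responses is the genotype difference after injection minus that before it, on the same arrays. A negative difference of responses with little difference afterwards gives higher levels before injection by construction. Feeding state and the mutation itself are untested.

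The largest differences between Gyc76C and yw larvae, such as CG3777 and CG32198, were weighed for their source. Loss of Gyc76C as the only difference is argued against by the Dif/Dl array after injection, whose signal lay nearer to Gyc76C than to yw for 62.1% of the 169 probe sets called before injection (exact interval 54.4 to 69.5), against 51.4% of all probe sets, if the Dif/Dl genotype itself does not move those genes. Chromosome 3, which carries Gyc76C, holds 37.4% of the 147 placed genes called before or after injection (exact interval 29.6 to 45.8). It holds 44.7% of all measured genes. This share cannot decide whether chromosome 3 is the only source, because a variant there can alter genes on other chromosomes. A segment around Gyc76C could account for a small part, as 6 of its 100 measured neighbours were called against 141 of 9867 other genes (odds ratio 4.4, interval 1.55 to 10.2, Fisher's exact p = 0.00355). Strain differences elsewhere and effects of Gyc76C at other loci both stay open, because the design holds 1 strain for each genotype.

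Toll pathway effectors lay higher after injection on the arrays labelled Dif/Dl by a median of 6.0, as in yw (4.80), although both factors belong to that pathway. A swap with larvae in which the Dif and dl region is intact is argued against, since the window of CG15141, Rsph9, CG5043, dl and CG5050 ranked among the lowest of 9909 windows in both states (0.676% at most). Signals near the top of the scanner range are argued against only weakly: the 3 effectors under 5000 had a median difference of 0.07 from yw, which just met its bound given a residual SD of 1.04. Some transcription from the region is an open candidate explanation, since all 5 probe sets from CG15141 to dl that were above the low-signal limit in yw were above it on both Dif/Dl arrays. Whether the larvae were homozygous is not given in the sources used here, and induction through other factors was not tested.

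Of 17 gene families grouped by symbol, 5 had responses that differed between the genotypes at the preset correlation and none did with an estimated one. Cytochrome P450 genes had a median difference of -0.16 (adjusted p = 0.00693, and adjusted p = 0.915 with an estimated correlation) and odorant-binding proteins one of -0.13 (0.0464 and 0.457). Mitochondrial ribosomal proteins had one of 0.17 (5.2e-05 and 0.915), aminoacyl-tRNA synthetases one of 0.27 (0.000197 and 0.457) and the 3 histone genes one of 0.46 (0.0352 and 0.457). Apart from the synthetases, each lost its call without single arrays: P450 genes without Gyc76C replicate 1 before injection (-0.03, adjusted p = 0.454), mitochondrial ribosomal proteins without Gyc76C replicate 1 after injection (0.01, adjusted p = 0.201), odorant-binding proteins without yw replicate 1 after injection (-0.10, adjusted p = 0.278) and histone genes without yw replicate 2 after injection (0.40, adjusted p = 0.0985), among others.

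A pair of the 183 control probe sets, which no comparison uses, had a high signal on the Dif/Dl arrays alone. AFFX-Dm-AF292560-1_s_at was 158 before and 26322 after injection, where the highest of the 8 other arrays was 9.14. AFFX-Dm-M62653-1_s_at was 205 and 21948, where the highest was 16.7. The cause of this gap between the Dif/Dl arrays was not tested, so a difference between them other than injection is not ruled out.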

How the results depend on the processing

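The alternatives for other lists, named genes and gene families were chosen only after the result was seen; those for counts of calls and for both effector lists were chosen before. With 2 arrays per group and MAS5 signals whose low end is noisy, precision is limited by the number of arrays and, for weak genes, by signal over background. Causes were not tested unless stated.

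In yw, 696 calls became 1359 with array weights, 1361 at an adjusted p under 0.10 and 384 with a change of at least 2-fold, the latter by their construction. In Gyc76C mutants 235 became 430 at an adjusted p under 0.10, and for the genotypes before injection 169 became 261 at that threshold and 99 without the eBayes trend. Median centring moved the share of higher calls before injection from 65.1% to 55.1%.

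With the replicate number as a block, calls rose to 1824 in yw, 998 in Gyc76C mutants, 384 before and 186 after injection, and kept 695, 235, 168 and 79 of the former calls. In this fit the share of higher calls moved from 51.1% to 47.3% in yw and from 56.6% to 40.2% in Gyc76C mutants. It moved from 65.1% to 54.4% before and from 53.2% to 44.6% after injection. Replicate differences correlated at 0.17, 0.19, 0.18, 0.084, 0.22 and 0.42 between groups, the last between both states of Gyc76C mutants. All but 1 are over 0.1, so a pairing is neither given by the labels nor ruled out, and the block was not used for the results above.

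Leaving out each of 8 arrays gave 95 to 982 calls in yw, 124 to 309 in Gyc76C mutants, 0 to 4 for the difference of responses, 28 to 214 before and 18 to 91 after injection. Fewer arrays are one cause of the lower counts; the lone array is assumed to vary like the other groups. Under these fits the Toll effectors ranged from 4.70 to 5.39 in yw and 3.97 to 5.03 in Gyc76C mutants and the IMD effectors from 1.98 to 2.59 and from 2.29 to 4.11, all past the threshold. For the difference of responses the ranges were -0.73 to 0.40 for Toll and -0.24 to 1.02 for IMD effectors, before injection -0.11 to 0.99 and -0.05 to 0.38, and after injection -0.05 to 0.76 and -0.02 to 1.17, so these signs depended on single arrays. The digestive enzyme difference ranged from -0.90 to -0.29 and was called in 8 of 8 fits.

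An estimated correlation leaves medians unchanged. It ended the calls of Toll effectors in yw (4.80, adjusted p = 0.151) and Gyc76C mutants (4.20, adjusted p = 0.114). The same held for IMD effectors (2.16, adjusted p = 0.229, and 3.29, adjusted p = 0.143). By fry, Toll effectors kept their calls in yw and Gyc76C mutants (adjusted p = 0.00187 and 0.00225), as did IMD effectors (adjusted p = 0.0456 and 0.0268). The digestive enzyme difference lost its call with an estimated correlation (-0.63, adjusted p = 0.847) and by fry (-0.63, adjusted p = 0.861). The Toll difference of responses reversed from -0.05 to 0.09 at pseudocount 64 (adjusted p = 0.799), uncalled in both; the cause was not tested. Cytosolic ribosomal proteins in yw reversed from -0.13 to 0.03 with quantile normalization (adjusted p = 0.847; the cause was not tested) and ranged from -0.25 to 0.01 when 1 array was left out, reversed without yw replicate 2 after injection.

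Of 2800 recomputed values of 156 pairs of a named gene and a comparison, 2455 stayed on their side of the threshold, 343 lost their call, 2 gained one and 0 reversed; 283 of the losses came from leaving out an array and 23 from dropping the trend. Of the 22 other called lists, 22 lost their call with an estimated correlation, 12 by fry, 4 with quantile normalization and 3 at the 60th percentile filter, and 18 of 176 values did so when an array was left out.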

Other observations

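All gene families in this part and their tests were chosen only after the result was seen.

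Genes of mitochondrial function had lower signals after injection in all 3 genotypes, as far as their medians show. The 69 mitochondrial ribosomal proteins, which serve translation inside mitochondria, had a median log2 change of -0.49 in yw (adjusted p = 2.27e-18, and adjusted p = 0.313 with an estimated correlation), with 68 of 69 below 0 and 12 that fell. In Gyc76C mutants it was -0.29 (adjusted p = 1.55e-11, and adjusted p = 0.523 with an estimated correlation), with 67 below 0 and 0 called by limma, and on the single Dif/Dl arrays -0.33. The 72 subunits of respiratory complexes had a median of -0.51 in yw (adjusted p = 2.34e-08, and adjusted p = 0.62 with an estimated correlation), with 57 below 0 and 1 that fell. Their median was -0.51 in Gyc76C mutants (adjusted p = 6.77e-10, and adjusted p = 0.54 with an estimated correlation), with 61 below 0 and 0 called by limma. On the Dif/Dl arrays it was -0.55. Genes of body wall muscle, a tissue rich in mitochondria, moved with them: their medians were -0.44 in yw and -0.35 in Gyc76C mutants, with 11 of 11 below 0 in each (adjusted p = 0.508 and 0.586 with an estimated correlation), and -0.68 on the Dif/Dl arrays.

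The Cpr and Twdl families, which encode cuticle proteins, had medians of -0.97 in yw (adjusted p = 1.62e-10, and adjusted p = 0.313 with an estimated correlation) and -0.76 in Gyc76C mutants (adjusted p = 2.49e-12, and adjusted p = 0.251 with an estimated correlation). Of 61 genes, 11 fell and 1 rose in yw, and 8 fell and 1 rose in the mutants. Serpin genes, whose products inhibit serine proteases, had medians of 0.28 (adjusted p = 0.0264, and adjusted p = 0.313 with an estimated correlation) and 0.38 (adjusted p = 0.0136, and adjusted p = 0.251 with an estimated correlation), and 2 of 17 rose in each genotype. That family lost its call without yw replicate 1 after injection in yw (0.32, adjusted p = 0.11) and without Gyc76C replicate 2 after injection in the mutants (0.25, adjusted p = 0.0518). The genes Cpr49Ae and Cpr64Aa are members of the cuticle list as well.

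The genes with the largest genotype differences were also read on the Dif/Dl arrays. CG3777, which lies near y in the gene order of the assembly Release 6 plus ISO1 MT, had signals of 2515 before and 1077 after injection in Dif/Dl larvae, against a mean of 5.51 in yw before injection. CG32198 had 16020 and 11640 there. Set against the means before injection given above, on a log scale, CG3777 lay nearer to Gyc76C mutants and CG32198 nearer to yw. Cyp6g1 had 7402 and 4934, NimC1 808 and 816 and Rnf11 220 and 215 in Dif/Dl larvae, which are not set against the other genotypes here.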
